A study of Mus musculus with 9 samples.

How the data were processed

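Transposon insertions were read in 9 libraries from mouse brain, 3 each from cortex, midbrain and hindbrain. Per the labels, wild-type CD-1 IGS mice received adeno-associated virus carrying the calling cards reagents by transcranial injection on postnatal day 1, and the regions were dissected on postnatal day 21. Calling cards mark where a DNA-bound protein has been: a piggyBac transposase drops a transposon near it, and the transposon's own transcript later reports the site. Here the record was read as one of BRD4, a chromatin reader that binds acetylated histones. The libraries were made from total RNA by reverse transcription with an oligo(dT) primer, PCR of the self-reporting transcripts and Nextera XT tagmentation.

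The deposited files are insertion tables in which each line holds a position, a strand, a barcode and a read count; the values are raw read counts with no normalization. Per the labels, reads were placed on the mm10 genome and Trimmomatic, BWA and SAMtools were used, with no versions given; filters and any pooling are not stated. Every interval was 4 bp wide, no combination of position, strand and barcode was repeated within a library, and 22 barcodes occurred. Reads of an insertion are PCR copies, so an insertion, not a read, was counted once whatever its read number. Of 3503694 insertions, 3503147 lay on chromosomes 1 to 19 and X and were used.

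Insertions were counted at 21755 protein-coding gene loci (GENCODE M21), each a gene body with 5 kb on both sides, and in 10 kb windows. An insertion in overlapping loci counted for each, and 65.2% of loci overlapped at least 1 other. Loci and windows with low counts were removed with filterByExpr of edgeR, libraries were scaled by TMM factors, and all 9 libraries were fitted together by the quasi-likelihood method of edgeR. Levels are given as CPM, counts per library scaled to a common total by TMM factors, of loci or of windows, as mean ± SD with n = 3 libraries per region. CPM of single libraries in the text, CPM of a read class, hindbrain to cortex ratios and differences of midbrain replicate 3 leave out the TMM factors. Fold changes are on the log2 scale with SE, p-values are two-sided, and adjustment was by Benjamini-Hochberg over all loci or windows of a contrast with a threshold of 0.05. The common biological coefficient of variation over loci was 0.145.

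The choices in this and the next paragraph were made before the data were examined. Named loci were, per contrast, the 8 with the smallest adjusted p in each direction among those past the threshold with an absolute log2 fold change of at least 1 and no overlap between libraries of both regions; predicted genes were skipped, and of overlapping loci the one with the smallest p was kept. From each gene list up to 3 members with the smallest p were added, and 4 windows per direction at least 50 kb apart. Repeats between contrasts are named fewer times.

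The 17 lists held telencephalic transcription factors, midbrain transcription factors, thalamic genes, Hox cluster genes, cerebellar neuron genes, brainstem neuron genes, monoaminergic and cholinergic neuron genes, cortical excitatory neuron genes, forebrain interneuron genes, striatal neuron genes, hippocampal neuron genes, astrocyte genes, oligodendrocyte lineage genes, microglial genes, vascular genes, activity-regulated genes and housekeeping genes. They were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Only loci past the low-count filter were tested, so some lists rest on few of their members. Among them were 4 of 25 midbrain transcription factor, 4 of 23 brainstem, 4 of 18 monoaminergic and cholinergic, 5 of 19 microglial and 4 of 20 vascular loci. Some genes are in several lists, and 25 of the 27 Hox loci overlap another Hox locus, so that their counts are not independent. Overlaps within a list also held for 4 forebrain interneuron, 4 cerebellar, 3 microglial, 2 thalamic, 2 brainstem and 2 monoaminergic and cholinergic loci.

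The share of insertions within 5 kb of a transcription start, in gene bodies and in neither was set against the share of genome length in each class. The design called for TTAA sites, where piggyBac inserts, as the baseline and for an alternative kept to TTAA; both need the genome sequence and were not run. Shares were compared by exact two-sided permutation tests. The 1000 densest windows of each library, after thinning to 127404 insertions, were compared between libraries.

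Alternatives were RLE factors, other low-count filters, other locus and window definitions, insertions with at least 3 reads, barcodes ignored, insertions found in several libraries left out, equal numbers of insertions (reads per insertion were not matched), DESeq2, a replicate block, only the regions compared and each library left out in turn. Leaving out insertions with under 5% of the reads that the same position, strand and barcode had in another library was added after the data were seen. Read-class values at named loci give ratios of pooled counts; with 1 to 3 insertions in a group the ratio has a 95% exact counting interval, and with 0 the floor was 3 insertions over the group. Intervals and floors cover counting error only.

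The procedure was tested on simulated data with 200 changed loci per contrast, 100 at each of 2 fold sizes. It recovered 29% of 2-fold and 94% of 4-fold changes for cortex against hindbrain, 57% and 98% for cortex against midbrain, and 33% and 87% for midbrain against hindbrain. Unchanged loci made up 10.9%, 4.91% and 6.98% of the calls, and of 16 unmoved lists camera called 0 in each contrast. Those lists were randomly drawn loci simulated independently. They therefore do not test the preset correlation on lists of correlated loci, such as the Hox list with an estimated correlation of 0.559.

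The labels do not say whether libraries of a region come from different animals, nor whether equal replicate numbers share an animal, so the p-values describe the spread between these libraries. Software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.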

Results

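The data are sites of transposon insertion in cortex, midbrain and hindbrain of mice, 3 libraries per region. Cortex libraries held 709254, 695742 and 526774 insertions, midbrain libraries 578982, 332418 and 182951, and hindbrain libraries 208685, 127421 and 141467. Insertions backed by a single read made up 14.3%, 20.5% and 22.7% of the cortex libraries, 19.7%, 30.2% and 36.9% of the midbrain libraries, and 33.4%, 49.1% and 51.8% of the hindbrain libraries. Depth and the single-read share thus moved with region. Loci are therefore given with all insertions, and many of the named ones also with insertions of at least 3 reads, as pooled ratios. The series describes its purpose as comparing BRD4 binding between brain regions, which each contrast below addresses.

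Between cortex and hindbrain, the loci with the strongest evidence included Hox and forkhead genes, higher in hindbrain, and loci of several cell types and functions. Foxb1, a forkhead transcription factor of the developing brainstem and hypothalamus, held 575 ± 118 CPM in hindbrain and 27.1 ± 3.68 in cortex, a 21.2-fold difference. Hoxa3, which sets segment identity in the caudal hindbrain, held 272 ± 139 CPM in hindbrain and 6.75 ± 2.23 in cortex (38.8-fold), and Pax3, a dorsal neural tube factor, 528 ± 132 and 19.6 ± 8.75 (27.7-fold). In the other direction Foxg1, needed for the telencephalon to form, held 840 ± 63.5 CPM in cortex and 338 ± 102 in hindbrain (2.55-fold), and Satb2, a factor of callosal projection neurons, 455 ± 201 and 107 ± 5.09 (4.28-fold). The astrocyte bicarbonate transporter gene Slc4a4 held 5566 ± 321 CPM in hindbrain and 1778 ± 334 in cortex (3.13-fold).

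The log2 fold change of cortex over hindbrain was -4.40 ± 0.27 (SE) for Foxb1 (chromosome 9, 69757710 to 69760940, mm10; adjusted p = 1.48e-12), -5.28 ± 0.40 for Hoxa3 (chromosome 6, 52169062 to 52213336; 8.95e-11) and 1.35 ± 0.21 for Foxg1 (chromosome 12, 49382660 to 49386861; 6.69e-05). Other loci higher in hindbrain were Irx5, an Iroquois homeobox gene (15.4-fold), Itpkb, an inositol trisphosphate kinase gene (4.14-fold), and Trpm3, which encodes a cation channel (3.75-fold). Other loci higher in cortex were Otx1, a homeobox gene of deep cortical layers (5.21-fold), Zfp800 (4.34-fold), Dph6 (2.91-fold), Fam172a (2.73-fold), Nrg1, which encodes a neuregulin (2.44-fold), and Gria2, an AMPA receptor subunit gene (2.36-fold). Pola1 (4.02-fold) overlaps the locus of Arx, a homeobox gene of interneurons (3.45-fold). Fam172a was not called when each insertion went to the nearest start site (log2 fold change 0.49), nor was Foxg1 when barcodes were ignored (0.40).

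At loci higher in cortex, single-read insertions were common in the hindbrain libraries: 60.1% of hindbrain insertions at the 246 loci higher in cortex had 1 read, against 41.8% at all tested loci and 30.7% at the 313 loci higher in hindbrain. At Foxg1 this share was 94.0% in hindbrain (110 of 117 insertions) and 14.2% in cortex. With at least 3 reads Foxg1 held 976 insertions in cortex and 2 in hindbrain, a pooled ratio of 88.8 (95% interval 24.5 to 734). Satb2 held 560 and 3 (ratio 34.0, 11.6 to 165), and Neurod6, a factor of excitatory cortical neurons, 279 and 3 (16.9, 5.73 to 82.5). Arx held 420 and 0, at least 25.5-fold higher in cortex. Other ratios of cortex over hindbrain were 30.0 for Otx1 (165 and 1; 5.31 to 1193), 14.2 for Pola1, 13.3 for Zfp800, 10.2 for Dph6, 5.43 for Nrg1, 4.41 for Fam172a and 3.95 for Gria2. Hoxa3 held 85 in hindbrain and 0 in cortex, at least 156-fold higher. Foxb1 held 172 and 9 (ratio 105), Pax3 160 and 2 (440, 120 to 3663), Hoxb3 103 and 2 (283, 76.4 to 2369) and Irx5 50 and 3 (91.6, 29.6 to 459).

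**Figure D1:**
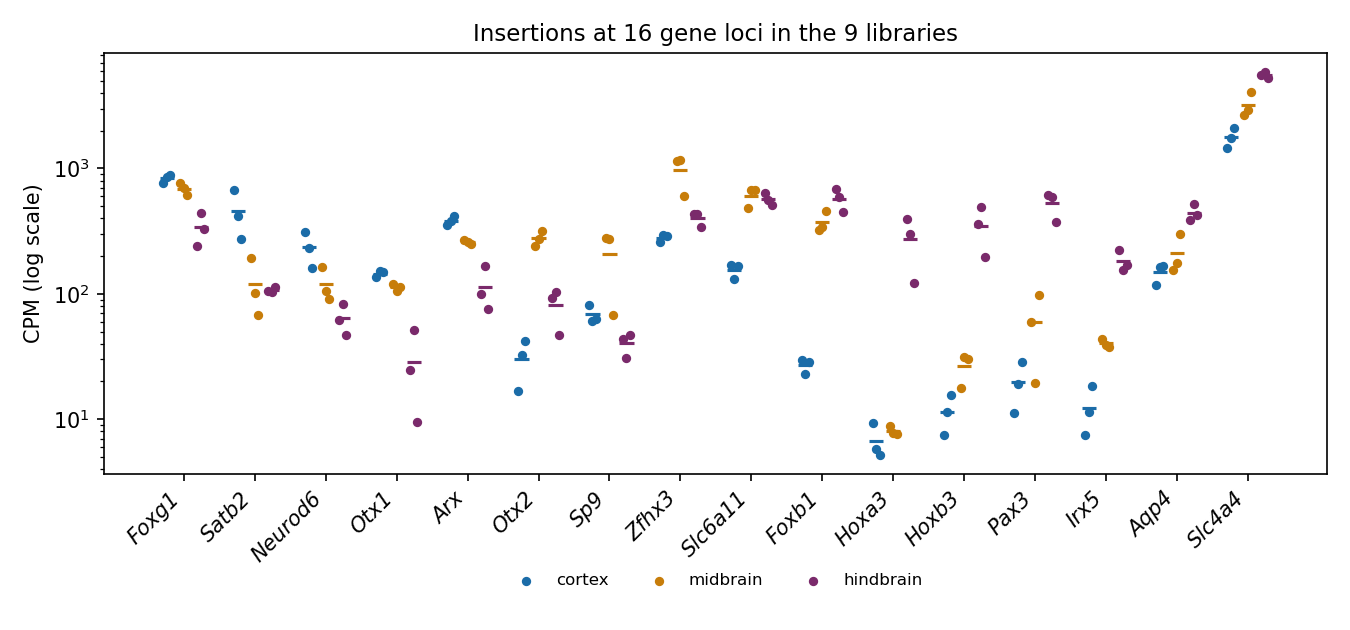
Insertions at 16 gene loci, in CPM on a log axis, for each of the 9 libraries (points, coloured by region) with the mean of each region (bar). Foxg1 lay at 840 in cortex and 338 in hindbrain on average, and Foxb1 at 27.1 and 575.

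**Figure D2:**
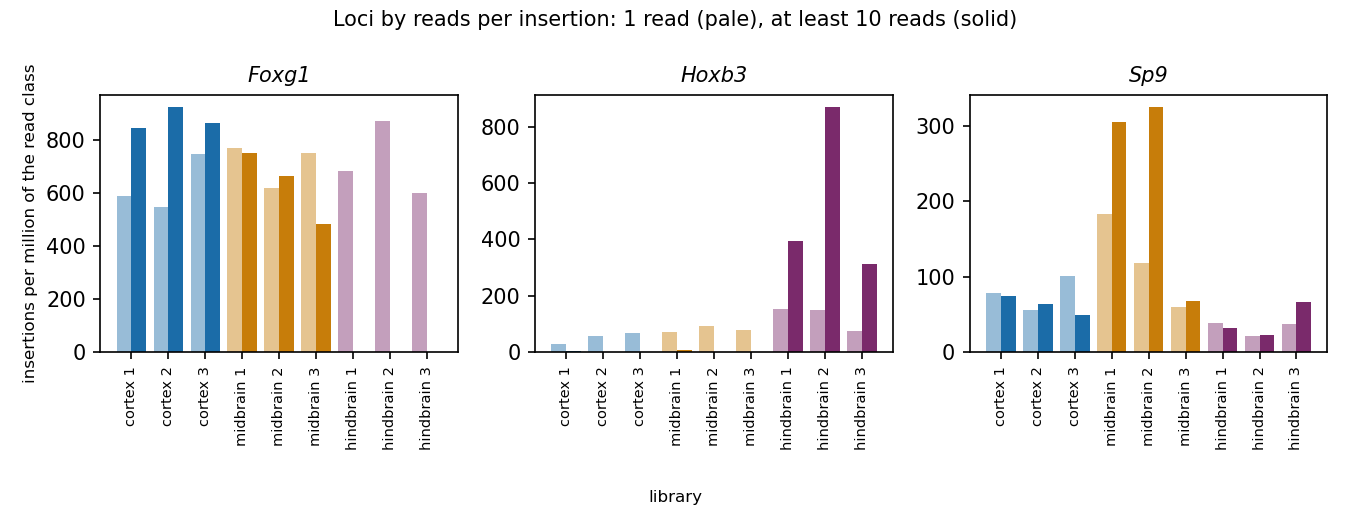
CPM within insertions of the same read class at Foxg1, Hoxb3 and Sp9 in each library, for insertions with 1 read (pale bars) and with at least 10 reads (solid bars), coloured by region as in the point plot of loci. Foxg1 had 797 insertions with at least 10 reads in cortex and 0 in hindbrain.

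By list, 10 of 23 tested telencephalic transcription factor loci were higher in cortex and 1 in hindbrain (14 and 1 adjusted over the list alone; camera adjusted p = 0.000266; adjusted p = 0.128 with an estimated correlation). The exception was Bhlhe40, an activity-responsive repressor found in many cell types. Of 20 cortical excitatory neuron loci, 7 were higher in cortex, with Satb2, Neurod6 (3.73-fold) and Mef2c (2.07-fold) among them, and 2 in hindbrain (11 and 2 adjusted over the list alone; adjusted p = 0.00153; adjusted p = 0.370 with an estimated correlation). Mef2c turned to -0.12 (log2) when insertions went to the nearest start site. Forebrain interneuron loci gave 4 of 14 higher in cortex, with Arx and Satb1 (2.59-fold) among them, and 1 in hindbrain, the receptor gene Erbb4 (3.27-fold). Adjusted over the list alone the counts were 5 and 1 (adjusted p = 0.0317; adjusted p = 0.445 with an estimated correlation). That call ended without cortex replicate 1 (0.125), hindbrain replicate 1 (0.0586) or hindbrain replicate 3 (0.0719). It also ended with no low-count filter (0.0601), a mean of at least 20 insertions (0.0845), gene bodies alone (0.284), nearest start sites (0.155), insertions found in several libraries left out (0.122), equal numbers of insertions (0.107) or fry (0.162), in a range over its alternatives of 0.00675 to 0.445.

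All 9 tested Hox loci of 27 listed were higher in hindbrain, also when adjusted over the list alone, with Hoxb3 at 30.3-fold and Hoxb4 at 27.0-fold (adjusted p = 7.02e-21; adjusted p = 0.0852 with an estimated correlation). Of 4 tested midbrain transcription factor loci of 25 listed, Irx5, Irx1 and Otx2 were higher in hindbrain and Nr4a2 in cortex. The counts were the same when adjusted over the list alone (camera adjusted p = 0.00204, and 0.111 with an estimated correlation). That list was not called without hindbrain replicate 1 (0.0586), hindbrain replicate 3 (0.102) or midbrain replicate 2 (0.0677). Nor was it called with a mean of at least 20 insertions (0.869), gene bodies alone (0.0822), nearest start sites (0.314) or equal numbers of insertions (0.0930), in a range of 0.000129 to 0.869. Otx2 was not called without cortex replicate 1 (log2 fold change -1.15), hindbrain replicate 1 (-1.32) or hindbrain replicate 2 (-1.34). Its call also ended with at least 3 reads (-1.77; 8 insertions in hindbrain and 12 in cortex), with insertions found in several libraries left out (-1.82) or with equal numbers of insertions (-1.19). Cerebellar neuron loci gave 6 of 15 higher in hindbrain, with Zic4 (3.35-fold), Zic1 (3.04-fold) and the Purkinje cell receptor gene Grid2 (2.19-fold), and 1, Neurod1, in cortex (6 and 2 adjusted over the list alone; adjusted p = 0.00634; adjusted p = 0.237 with an estimated correlation). The cerebellar list was not called without cortex replicate 1 (0.0864), with a mean of at least 20 insertions (0.0845), with at least 3 reads (0.182), with insertions found in several libraries (0.0921) or under 5% of another library (0.0588) left out, or with equal numbers of insertions (0.107; range 2.35e-07 to 0.237). Neurod1 was not called without cortex replicate 1 (1.53) or 2 (1.65), or without hindbrain replicate 1 (1.23), 2 (2.08) or 3 (1.77). Its call also ended with at least 3 reads (2.12), barcodes ignored (1.23), insertions found in several libraries (1.07) or under 5% of another library (1.35) left out, or DESeq2 (1.66). Of 25 astrocyte loci, 6 were higher in hindbrain and 0 in cortex (8 and 0 adjusted over the list alone), with Slc4a4, the water channel gene Aqp4 (2.95-fold) and the connexin gene Gjb6 (2.23-fold); the adjusted p was 0.000273, and adjusted p = 0.445 with an estimated correlation; with fry it was 0.0973, in a range of 2.07e-07 to 0.445.

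The other 10 lists were not called between cortex and hindbrain, though 4 of them were under other settings. Thalamic loci gave 1 of 13 higher in cortex, Ntng1 (2.54-fold), and 3 in hindbrain, 1 and 4 adjusted over the list alone (adjusted p = 0.0647). Oligodendrocyte lineage loci gave 2 of 7 higher in hindbrain, Enpp2 (2.80-fold) and Olig1 (1.77-fold), also over the list alone (0.0995). Striatal loci gave 2 of 10 higher in hindbrain, Ebf1 (4.67-fold) and Foxp2 (1.86-fold), also over the list alone (0.822). Hippocampal loci gave 2 of 9 higher in cortex, Neurod1 and Mpped1, and 1, Calb1, in hindbrain, 3 and 1 over the list alone (0.706), with a median log2 fold change of -0.05 where the mean, 0.19, and the test pointed to cortex. Of the vascular, activity-regulated and housekeeping loci, 1 each was called, Rgs5 and Egr4 in cortex and Ubc (1.71-fold) in hindbrain (adjusted p = 0.241, 0.389 and 0.394 for the lists), with the same counts over each list alone. Egr4 rested on 48 cortex insertions and 1 in hindbrain, a pooled ratio of 12.3 (95% interval 2.10 to 495), so fitted values of Egr4 without a library are not given. Brainstem, monoaminergic and cholinergic, and microglial loci gave 0 calls by edgeR in 4, 4 and 5 tested (0.394, 0.394 and 0.706), 0 by DESeq2, 0 over each list alone and 0 at an unadjusted p under 0.05. Without hindbrain replicate 1 the calls of Olig1 (log2 fold change -0.89), Foxp2 (-0.67), Calb1 (-2.28), Mpped1 (0.98), Rgs5 (1.67), Egr4 and Ubc (-0.79) ended. Without hindbrain replicate 3 those of Olig1 (-0.72), Foxp2 (-0.97), Calb1 (-1.84), Mpped1 (1.44) and Rgs5 (1.98) ended, and without hindbrain replicate 2 those of Rgs5 (1.63), Egr4 and Ubc (-0.74). Calls also ended without cortex replicate 1 for Olig1 (-0.70) and Mpped1 (1.15), without cortex replicate 2 for Foxp2 (-0.92), Mpped1 (1.46) and Ubc (-0.70), and without midbrain replicate 2 for Rgs5 (1.77). With at least 3 reads Olig1 (-0.70) and Ubc (-0.70) were not called, nor with insertions found in several libraries (-1.05 and -0.26) or under 5% of another library (-0.66 and -0.61) left out. With equal numbers of insertions the calls of Enpp2 (-0.92) and Ubc (-0.52) ended, and with barcodes ignored those of Foxp2 (-0.70) and Mpped1 (1.11). With nearest start sites those of Olig1 (-0.65) and Egr4 ended, with gene bodies alone that of Mpped1 (1.34) and with no low-count filter that of Ubc (-0.67). By DESeq2 Foxp2, Mpped1, Rgs5 and Egr4 were not called.

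The thalamic list was called between cortex and hindbrain with fry (adjusted p = 0.00206), no low-count filter (0.00221), gene bodies alone (0.0218) and nearest start sites (0.00670). It was also called without cortex replicate 3 (0.0481), hindbrain replicate 1 (0.0436), hindbrain replicate 2 (0.0395) or midbrain replicate 3 (0.0280), in a range over its alternatives of 0.00206 to 0.264. The oligodendrocyte lineage list was called with fry (0.00206), no low-count filter (0.00132), nearest start sites (0.00297) and barcodes ignored (0.0121), and without midbrain replicate 3 (0.0224), in a range of 0.00132 to 0.467. The brainstem list was called with no low-count filter (2.92e-05) and nearest start sites (0.0285), and without midbrain replicate 2 (0.0105) or 3 (0.0233), in a range of 2.92e-05 to 0.989. The activity-regulated list was called with nearest start sites (0.0310, the lowest of its alternatives, the highest being 0.908).

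In all, 559 of 5842 loci differed between cortex and hindbrain by edgeR, 246 higher in cortex and 313 in hindbrain, of which 182 and 190 by at least 2-fold, and 1374 had an unadjusted p under 0.05. Libraries of both regions did not overlap at 29.4% of loci, where chance gives 10%. The balance of directions depended on the processing, with 391 loci higher in cortex and 350 in hindbrain at 3 reads or more, 358 and 262 with no low-count filter, and 126 and 244 by DESeq2. Only 193 loci were called without hindbrain replicate 1, 309 without hindbrain replicate 2, 334 without hindbrain replicate 3, 320 without cortex replicate 2, 367 without cortex replicate 1, 318 with equal numbers of insertions and 370 by DESeq2. The calls of all 7 lists ended with an estimated correlation.

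In 10 kb windows, 1354 of 6715 differed between cortex and hindbrain, 677 in each direction, and 65.7% of these lay in genes. With a looser low-count filter, on the total of a window over all libraries, 966 were higher in cortex and 386 in hindbrain, and by DESeq2 315 and 490. The window with the strongest evidence held part of Foxb1 (chromosome 9, 69760001 to 69770000), with 355 ± 33.1 CPM in hindbrain and 21.7 ± 0.577 in cortex (adjusted p = 6.65e-11). Windows within Erbb4 (chromosome 1, 69020001 to 69030000, 10.4-fold), Trpm3 (chromosome 19, 22450001 to 22460000, 4.68-fold) and Meis1, a Hox cofactor gene (chromosome 11, 18870001 to 18880000, 7.56-fold), were also higher in hindbrain. The leading cortex windows lay outside genes: chromosome 1, 41740001 to 41750000 (3.70-fold) and 41820001 to 41830000 (3.84-fold), 934400 bp from the start of Tmem182 and 865768 bp from that of the neuronal POU factor gene Pou3f3, and windows 61716 bp from the start of BC052040 (4.02-fold) and 246451 bp from that of Mms22l (3.73-fold). The count was 586 without hindbrain replicate 1, 542 with equal numbers of insertions, 593 with barcodes ignored, 751 without insertions found in several libraries and 805 by DESeq2.

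**Figure D3:**
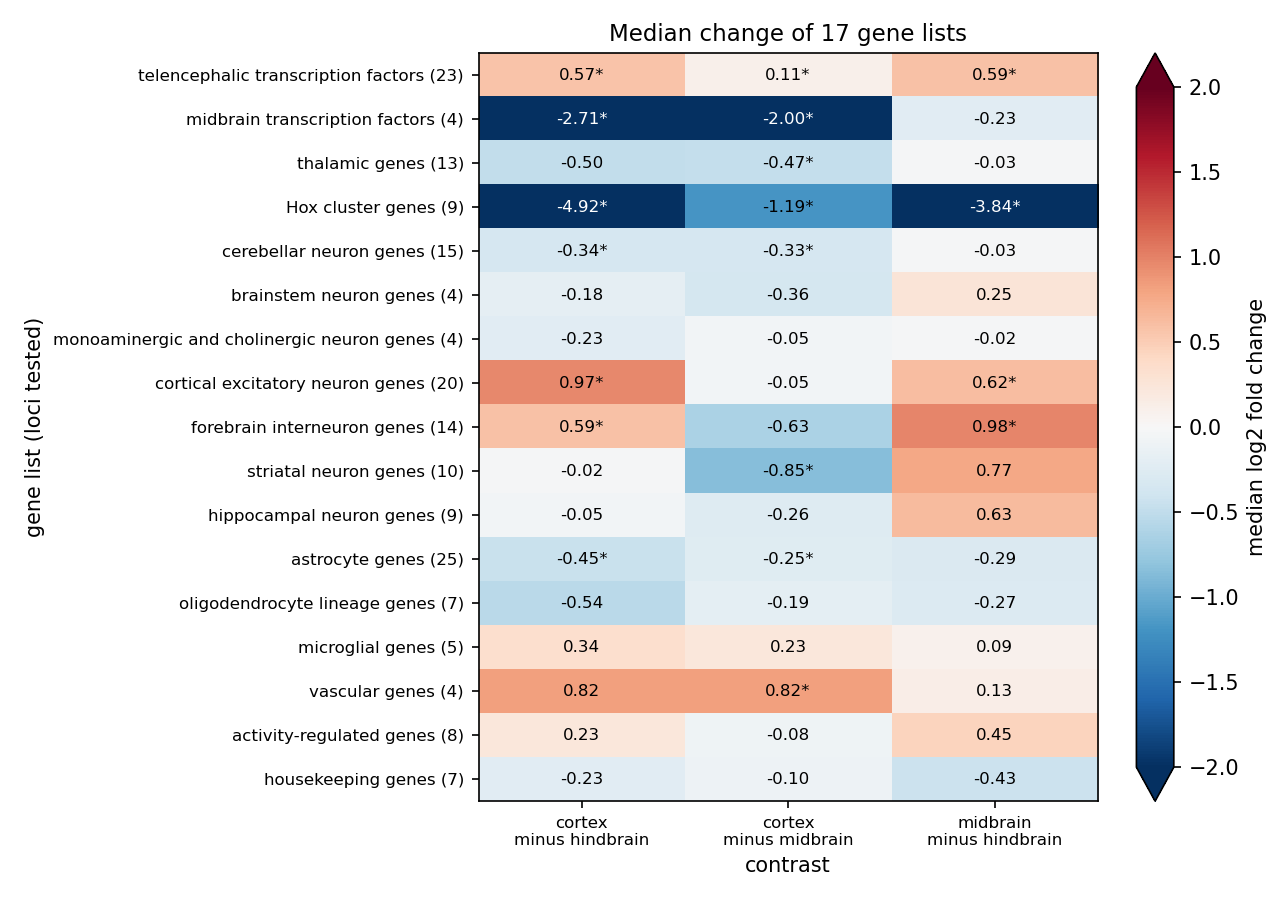
Median log2 fold change of the tested loci of 17 gene lists (lines of the grid) in 3 contrasts (columns); colour and number give the median, the number of loci stands in brackets, and a star marks a camera adjusted p under 0.05 at the preset correlation. The Hox list lay at -4.92 for cortex minus hindbrain and the cortical excitatory list at 0.97.

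Cortex and midbrain were closer, and most loci that differed were higher in midbrain. Otx2, a homeobox gene that specifies the midbrain, held 277 ± 38.0 CPM in midbrain and 30.3 ± 12.6 in cortex (9.12-fold), and Foxb1 373 ± 71.1 and 27.1 ± 3.68 (13.3-fold). Slc6a11, a GABA transporter gene, held 608 ± 109 CPM in midbrain against a cortex mean of 156 (3.85-fold), and Zfhx3, which encodes a zinc finger homeobox factor, 970 ± 317 and 281 ± 17.4 (3.52-fold). Satb2 was the locus with the strongest evidence higher in cortex, at 455 ± 201 CPM against 120 ± 63.8 in midbrain (3.42-fold). Foxg1, chosen here after its values were seen, held 690 ± 73.6 CPM in midbrain and 840 ± 63.5 in cortex and was not called (log2 fold change 0.27, adjusted p = 0.688).

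For Otx2 (chromosome 14, 48657677 to 48673819, mm10) the log2 fold change of cortex over midbrain was -3.19 ± 0.27 (adjusted p = 3.62e-09), and for Satb2 (chromosome 1, 56793981 to 56978650) it was 1.78 ± 0.28 (adjusted p = 0.000593). Zic4 and Zfhx4 were also higher in midbrain (3.15-fold and 2.70-fold), as were Lrig3 (2.83-fold) and Cables1 (2.12-fold). In cortex the loci of Cdkn2c, a cell cycle inhibitor gene (2.69-fold), Drosha, the microRNA processing enzyme gene (2.53-fold), Cavin1 (2.45-fold) and Hgf (2.19-fold) were higher. With at least 3 reads Otx2 held 177 insertions in midbrain and 12 in cortex, a pooled ratio of 27.2, and Foxb1 204 and 9 (41.7). Calls ended without cortex replicate 2 for Cdkn2c (log2 fold change 1.37), Hgf (1.17), Drosha (1.27), Cavin1 (1.35) and Cables1 (-0.99), and the first 4 also ended with barcodes ignored (0.97, 0.72, 0.96 and 0.74) and by DESeq2. Cdkn2c (1.26) and Hgf (1.15) ended with equal numbers of insertions, and Drosha and Cavin1 (1.45) with at least 3 reads. Both also ended with insertions under 5% of another library left out (1.31 and 1.47) and with only these regions fitted. Drosha ended with gene bodies alone (1.28), and Cavin1 with RLE factors (1.29). Without midbrain replicate 1 Cdkn2c (1.43), Hgf (1.12), Drosha (1.36) and Cavin1 (1.74) ended, and without midbrain replicate 2 Cdkn2c (1.24), Hgf (1.26), Drosha (1.28) and Cavin1 (1.19). Drosha also ended without cortex replicate 3 (1.24), and Cavin1 without cortex replicate 1 (1.08), midbrain replicate 3 (1.18), hindbrain replicate 1 (1.31) or hindbrain replicate 3 (1.302). Lrig3 ended when insertions went to the nearest start site (-0.69) and with equal numbers of insertions (-1.73).

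By list, 4 of 13 thalamic loci were higher in midbrain, namely Zic4, Zic1 (2.96-fold), Tcf7l2, a Wnt effector of thalamic neurons (2.15-fold), and Prox1 (2.73-fold), and 0 in cortex (6 and 0 adjusted over the list alone; adjusted p = 3.95e-06; adjusted p = 0.0211 with an estimated correlation). Of 4 midbrain transcription factor loci, Otx2 and Irx5 (3.42-fold) were higher in midbrain (3 adjusted over the list alone; adjusted p = 5.19e-06; adjusted p = 0.0211 with an estimated correlation). Those were the only lists still called with an estimated correlation, and the latter was not called when insertions went to the nearest start site (0.677, the highest of its alternatives, the lowest being 1.1e-07). Of 10 striatal loci, 3 were higher in midbrain, Sp9 (3.29-fold), Ebf1 (3.02-fold) and Pde10a (1.87-fold), with 7 adjusted over the list alone (adjusted p = 0.00158; adjusted p = 0.330 with an estimated correlation). The striatal call ended without midbrain replicate 1 (0.355), with equal numbers of insertions (0.0525) and with fry (0.364; range over its alternatives 5.9e-10 to 0.364). At Sp9 the midbrain libraries stood at 283, 275 and 65.7 CPM, the lowest being replicate 3.

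Of 15 cerebellar loci, Zic1 and Zic4 were higher in midbrain (4 adjusted over the list alone; adjusted p = 0.00299; adjusted p = 0.234 with an estimated correlation; 0.0821 with fry, in a range of 1.59e-05 to 0.234). Of 25 astrocyte loci, 1 was higher in midbrain, Slc4a4 (1.80-fold; 2 adjusted over the list alone; adjusted p = 0.00155; adjusted p = 0.498 with an estimated correlation); the list was not called without midbrain replicate 3 (0.543, the highest of its alternatives, the lowest being 1.6e-05), without cortex replicate 1 (0.125) or with fry (0.391). The Hox list was called towards midbrain with 0 of 9 loci called by edgeR, 0 by DESeq2, 0 over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 3.95e-06; adjusted p = 0.234 with an estimated correlation); Hoxa1, with the smallest p, held 33.2 ± 8.60 CPM in midbrain and 14.7 ± 8.08 in cortex. The Hox list was not called with at least 3 reads (0.264), with insertions found in several libraries (0.732) or under 5% of another library (0.0627) left out, with equal numbers of insertions (0.139) or with fry (0.193; range over its alternatives 4.26e-06 to 0.732). Telencephalic loci gave 1 of 23 higher in cortex, Satb2 (3 adjusted over the list alone; adjusted p = 0.00605; adjusted p = 0.234 with an estimated correlation), and the call ended without cortex replicate 1 (0.0570), with barcodes ignored (0.207) and with fry (0.193; lowest of all alternatives 0.000919). Vascular loci gave 0 of 4 by edgeR and by DESeq2, 4 at an unadjusted p under 0.05 and, adjusted over the list alone, 3 higher in cortex and 1 in midbrain (adjusted p = 0.0432; adjusted p = 0.288 with an estimated correlation). That call ended with any of the 9 libraries left out (0.127 without midbrain replicate 2 to 0.367 without cortex replicate 3), with fry (0.195), no low-count filter (0.116), nearest start sites (0.0916) or insertions found in several libraries left out (0.732), and turned direction with at least 3 reads (0.802, the highest of its alternatives, the lowest being 0.000929).

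The remaining 9 lists were not called between cortex and midbrain. Forebrain interneuron loci gave Sp9 and Sp8 (2.17-fold) higher in midbrain and Satb1 (1.86-fold) in cortex among 14 (5 and 2 adjusted over the list alone; adjusted p = 0.170); without midbrain replicate 3 this list was called towards midbrain (6.3e-07; range over its alternatives to 0.980). It was also called with no low-count filter (0.0297) and without cortex replicate 1 (0.00423) or hindbrain replicate 1 (0.0139), 2 (0.0213) or 3 (0.0225). Cortical excitatory loci gave 1 of 20, Satb2, in cortex, 3 with 1 in midbrain over the list alone (0.204), with a median of -0.05 where the mean, 0.10, and the test pointed to cortex. Hippocampal loci gave 1 of 9, Prox1, in midbrain, 2 over the list alone (0.0660). By edgeR 0 loci were called in the brainstem (0.121), monoaminergic and cholinergic (0.926), oligodendrocyte lineage (0.204), microglial (0.498), activity-regulated (0.824) and housekeeping (0.498) lists, and 0 by DESeq2; at an unadjusted p under 0.05 there were 1, 1, 2, 1, 1 and 0. Over each list alone 1 was called in the brainstem and activity-regulated lists, in midbrain, 1 in the monoaminergic and cholinergic list, in cortex, and 0 in the others. In the monoaminergic and cholinergic list median and mean were negative (-0.05 and -0.04) and the test pointed to cortex. The cortical excitatory list was called without cortex replicate 3 (0.0138) or midbrain replicate 1 (0.0178; range over its alternatives 0.0138 to 0.819), and the hippocampal list with barcodes ignored (0.0416) and without midbrain replicate 3 (0.0286; range 0.0286 to 0.958). The brainstem list was called without cortex replicate 1 (0.0242) or midbrain replicate 3 (0.01001, the lowest of its alternatives, the highest being 0.976). The oligodendrocyte lineage list was called with insertions found in several libraries left out (0.0391) and without cortex replicate 2 (0.0334; range 0.0334 to 0.408).

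In all, 58 of 5842 loci differed between cortex and midbrain by edgeR, 14 higher in cortex and 44 in midbrain, of which 6 and 32 by at least 2-fold, and 550 had an unadjusted p under 0.05. Libraries of both regions did not overlap at 13.9% of loci, where chance gives 10%. Without midbrain replicate 3 the count was 125, without midbrain replicate 2 it was 25 and without cortex replicate 2 it was 15; with equal numbers of insertions it was 22, with barcodes ignored 30, with no low-count filter 97 and with nearest start sites 90. Without cortex replicate 2 the calls of Tcf7l2 (log2 fold change -1.02), Prox1 (-1.34), Irx5 (-1.73), Sp8 (-1.06), Satb1 (0.96), Pde10a (-0.92) and Slc4a4 (-0.85) ended, and without midbrain replicate 1 those of Prox1 (-1.48), Irx5 (-1.67), Ebf1 (-1.25), Sp8 (-1.09) and Pde10a (-0.50). Without midbrain replicate 2 Prox1 (-1.39), Irx5 (-1.81), Sp8 (-0.84), Satb1 (0.72) and Pde10a (-0.95) ended, and without cortex replicate 1 Irx5 (-1.50), Sp8 (-1.08), Satb1 (0.75) and Pde10a (-0.91). Pde10a also ended without cortex replicate 3 (-0.89), and both Pde10a (-0.88, -0.90 and -0.89) and Satb1 (0.92, 0.90 and 0.91) without hindbrain replicate 1, 2 or 3. With nearest start sites Tcf7l2 (-0.60) and Irx5 (-0.45) ended and Pde10a turned to 0.03 (log2). With equal numbers of insertions Tcf7l2 (-1.01), Irx5 (-1.95), Ebf1 (-1.48), Sp8 (-0.32), Satb1 (0.81) and Pde10a (-0.79) ended. With barcodes ignored Irx5 (-1.48), Sp8 (-0.98), Satb1 (0.72) and Pde10a (-0.76) ended, and with insertions found in several libraries left out Satb1 (0.94) and Pde10a (-1.02). Satb1 also ended with at least 3 reads (1.07), and both Satb1 and Pde10a with a mean of at least 20 insertions (0.89 and -0.91) and with insertions under 5% of another library left out (0.95 and -1.01). Irx5 (-1.86) and Sp8 (-0.88) ended with gene bodies alone. Prox1, Irx5, Sp8 and Pde10a were not called by DESeq2, and Irx5, Sp8, Satb1, Pde10a and Slc4a4 not with only these regions fitted.

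Of 6715 windows, 260 differed between cortex and midbrain, 96 higher in cortex and 164 in midbrain, and 56.5% lay in genes. Higher in midbrain were windows in Otx2 (chromosome 14, 48670001 to 48680000, mm10, 12.8-fold), Foxb1 (chromosome 9, 69760001 to 69770000, 11.3-fold) and Zfhx3 (chromosome 8, 108240001 to 108250000, 9.97-fold), and 1 lying 15864 bp from the start of Kiz (chromosome 2, 146830001 to 146840000, 6.91-fold). All 4 leading cortex windows lay outside genes, 3 of them on chromosome 1 from 41670001 to 41830000 (3.11-fold, 4.17-fold and 3.35-fold) and 1 lying 61716 bp from the start of BC052040 (2.43-fold). The count was 121 without cortex replicate 2, 120 without midbrain replicate 2, 79 with equal numbers of insertions, 92 with barcodes ignored, 157 without insertions found in several libraries and 139 by DESeq2.

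Midbrain and hindbrain differed in both directions, with Sp9, Otx2 and Foxg1 among the loci higher in midbrain and Hoxa3 and Meis1 among those higher in hindbrain. Sp9, a factor of striatal and interneuron progenitors, held 207 ± 120 CPM in midbrain and 40.4 ± 8.38 in hindbrain (5.50-fold), and Otx2 277 ± 38.0 and 81.0 ± 29.9 (3.29-fold). Foxg1 held 690 ± 73.6 CPM in midbrain and 338 ± 102 in hindbrain (2.11-fold). Among insertions with at least 10 reads, Foxg1 held 750, 663 and 483 CPM of that read class in midbrain replicates 1, 2 and 3. The cortex libraries held 843, 923 and 863. Whether forebrain tissue in the midbrain dissections contributed to the loci higher in midbrain was not tested. Hoxa3 held 272 ± 139 CPM in hindbrain and 8.05 ± 0.660 in midbrain (32.7-fold), and Meis1 1077 ± 159 and 361 ± 59.9 (log2 fold change -1.59).

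The log2 fold change of midbrain over hindbrain was 2.46 ± 0.42 for Sp9 (chromosome 2, 73271925 to 73284706, mm10; adjusted p = 0.000559) and -5.03 ± 0.44 for Hoxa3 (adjusted p = 9.12e-09). Also higher in midbrain were Asb4 (3.95-fold), Ptprn2, a secretory vesicle protein gene (2.79-fold), Hapln1, a gene of the extracellular matrix around neurons (2.65-fold), Zfhx3 (2.45-fold) and Gria2 (2.11-fold). Dlx5, a homeobox gene of interneurons, held 100 insertions in midbrain and 6 in hindbrain (6.88-fold). Higher in hindbrain were Hoxb3 (14.3-fold), Pax3 (9.84-fold), Hoxa1 (7.21-fold), Rnf220, a ubiquitin ligase gene (4.73-fold), Mob3b (3.89-fold) and Cntn1, a cell adhesion gene (2.93-fold). With at least 3 reads Foxg1 held 421 insertions in midbrain and 2 in hindbrain (pooled ratio 70.5, 95% interval 19.4 to 584), and Dlx5 85 and 0, at least 9.49-fold higher in midbrain. The ratio was 12.6 for Asb4 (113 and 3; 4.21 to 62.1), 8.33 for Hapln1, 7.41 for Otx2, 5.17 for Ptprn2 and 3.41 for Gria2. Towards hindbrain it was 254 for Hoxa3 (85 and 1; 44.3 to 10141), 154 for Hoxb3 (103 and 2; 41.5 to 1287), 18.2 for Hoxa1, 17.1 for Pax3 and 6.43 for Mob3b. Without hindbrain replicate 1 the calls of Hapln1 (log2 fold change 1.22), Dlx5 (2.52) and Foxg1 (0.84) ended. Foxg1 was also not called with nearest start sites (0.57) or with barcodes ignored (0.63), and Dlx5 not by DESeq2 (2.73).

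By list, 6 of 14 forebrain interneuron loci were higher in midbrain, Sp9, Arx and the overlapping pairs Dlx1 with Dlx2 and Dlx5 with Dlx6, and 1, Erbb4 (2.12-fold), in hindbrain (8 and 1 adjusted over the list alone; adjusted p = 0.00214; adjusted p = 0.538 with an estimated correlation). That call also ended with gene bodies alone (0.119), with equal numbers of insertions (0.224) and with fry (0.0839), in a range of 9.9e-08 to 0.538. Midbrain replicate 3 lay below the other midbrain libraries at 13 of these 14 loci, by a median log2 difference of 1.36, with Dlx5 at 125, 149 and 43.8 CPM in midbrain replicates 1, 2 and 3 and Dlx6 at 199, 184 and 43.8. Of 20 cortical excitatory loci, 3 were higher in midbrain, Fezf2 (2.84-fold), Hs3st4 (2.62-fold) and Nr4a2 (3.45-fold), and 0 in hindbrain (8 and 1 adjusted over the list alone; adjusted p = 0.00915; adjusted p = 0.538 with an estimated correlation; 0.127 with fry, in a range of 0.000156 to 0.538), and midbrain replicate 3 lay below the other midbrain libraries at 17 of the 20 (median log2 difference 0.480). Of 23 telencephalic loci, 4 were higher in midbrain, Foxg1, Fezf2, Bcl11b (2.98-fold) and Foxp1 (1.72-fold), and 1, Bhlhe40, in hindbrain (8 and 1 adjusted over the list alone; adjusted p = 0.0266; adjusted p = 0.538 with an estimated correlation). Without hindbrain replicate 1 and without midbrain replicate 1 the telencephalic list was not called (0.110 and 0.0997), nor with fry (0.0600; lowest of all alternatives 0.000155). All 9 tested Hox loci were higher in hindbrain, also over the list alone, with Hoxb4 at 12.8-fold; DESeq2 called 5 of them (adjusted p = 1.93e-21; adjusted p = 0.0799 with an estimated correlation).

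The remaining 13 lists were not called between midbrain and hindbrain. Astrocyte loci gave 2 of 25 higher in hindbrain, Aqp4 (2.22-fold) and Slc4a4 (1.74-fold), 3 adjusted over the list alone (adjusted p = 0.0538); without midbrain replicate 3 the list was called (0.000122, the lowest of its alternatives, the highest being 0.604). Striatal loci gave 2 of 10, Sp9 and Foxp1, higher in midbrain, 4 over the list alone (adjusted p = 0.155), and without midbrain replicate 3 the list was called (2.7e-05, the lowest of its alternatives, the highest being 0.760). Midbrain transcription factor loci gave Otx2 and Nr4a2 higher in midbrain and Irx5 (4.50-fold) and Irx1 (5.34-fold) in hindbrain (0.395). Thalamic loci gave Prox1 (5.15-fold) and Ntng1 (1.91-fold) among 13, with a median of -0.03 and a mean of 0.25 (0.360). Cerebellar loci gave 1 of 15, Grid2 (2.15-fold), in hindbrain, 2 and 1 in midbrain over the list alone (0.360), hippocampal loci 1 of 9, Prox1, 3 and 1 over the list alone (0.218), and activity-regulated loci 1 of 8, Egr4 (0.246), with 33 insertions in midbrain and 1 in hindbrain (pooled ratio 14.4, 95% interval 2.41 to 585). By edgeR 0 loci were called in the brainstem (0.843), monoaminergic and cholinergic (0.360), oligodendrocyte lineage (0.350), microglial (0.993), vascular (0.993) and housekeeping (0.586) lists, and 0 by DESeq2; at an unadjusted p under 0.05 there were 0, 1, 2, 0, 0 and 2. Over each list alone 1 was called in the monoaminergic and cholinergic list, in hindbrain, and 0 in the others. The microglial median was 0.09 and its mean -0.04.

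Some of these 13 lists were called between midbrain and hindbrain under other settings. The astrocyte list was also called with no low-count filter (adjusted p = 0.00529), a mean of at least 20 insertions (0.0415), nearest start sites (0.0182) and barcodes ignored (0.00562), and without hindbrain replicate 1 (0.0210) or 3 (0.0107). The striatal list was also called with no low-count filter (0.00500), nearest start sites (0.0297) and barcodes ignored (0.0400). It was called, too, without cortex replicate 1 (0.0348), 2 (0.0317) or 3 (0.0419) and without hindbrain replicate 2 (0.00903) or 3 (0.00626). The hippocampal list was called with at least 3 reads (0.0275) and barcodes ignored (0.0371), and without cortex replicate 1 (0.0216), 2 (0.0205) or 3 (0.0255) or midbrain replicate 1 (0.0342), in a range over its alternatives of 0.0205 to 0.808. With no low-count filter the midbrain transcription factor (0.0338; range 0.0338 to 0.907), cerebellar (0.0319; range 0.0319 to 0.828) and oligodendrocyte lineage (0.0458; range 0.0146 to 0.933) lists were called. The brainstem list was then called in the other direction (0.00168; range 0.00168 to 0.992), as was the midbrain transcription factor list with a mean of at least 20 insertions (0.0415). With nearest start sites the oligodendrocyte lineage (0.0146) and activity-regulated (0.0182; range 0.0182 to 0.890) lists were called, and with fry the thalamic list (0.0335; range 0.0335 to 0.925).

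In all, 210 of 5842 loci differed between midbrain and hindbrain by edgeR, 97 higher in midbrain and 113 in hindbrain, of which 79 and 83 by at least 2-fold, and 989 had an unadjusted p under 0.05. Libraries of both regions did not overlap at 18.9% of loci, where chance gives 10%. With at least 3 reads 369 loci were called, 183 of them among the 210, with 202 higher in midbrain and 167 in hindbrain. With no low-count filter 148 and 111 were called in these directions; counts were 489 without midbrain replicate 3, 85 without midbrain replicate 1, 103 without midbrain replicate 2, 49 without hindbrain replicate 1, 97 without hindbrain replicate 2, 109 without hindbrain replicate 3, 124 with equal numbers of insertions, 129 with barcodes ignored and 139 by DESeq2. Without hindbrain replicate 1 the calls of Fezf2 (log2 fold change 1.45), Bcl11b (1.41), Irx1 (-2.32), Prox1 (2.25), Ntng1 (0.88), Hs3st4 (1.29), Nr4a2 (1.80), Erbb4 (-0.95), Foxp1 (0.73), Slc4a4 (-0.81) and Egr4 ended. Without hindbrain replicate 2 Bcl11b (1.59), Irx1 (-2.40), Ntng1 (0.98), Hs3st4 (1.48), Nr4a2 (1.61), Foxp1 (0.79), Aqp4 (-1.05), Slc4a4 (-0.77) and Egr4 ended. Without hindbrain replicate 3 Fezf2 (1.22), Bcl11b (1.63), Ntng1 (0.88), Hs3st4 (1.32), Nr4a2 (1.91), Foxp1 (0.75) and Egr4, then with 0 hindbrain insertions, ended. Without midbrain replicate 1 Bcl11b (0.90), Irx1 (-2.07), Ntng1 (0.93), Hs3st4 (1.24), Nr4a2 (1.43), Foxp1 (0.50), Aqp4 (-0.93) and Slc4a4 (-0.67) ended. Without midbrain replicate 2 Irx1 (-2.12), Hs3st4 (1.31), Nr4a2 (1.67), Foxp1 (0.79), Aqp4 (-1.05), Slc4a4 (-0.74) and Egr4 ended. Ntng1 also ended without midbrain replicate 3 (0.69), and Ntng1 (0.94), Nr4a2 (1.77) and Foxp1 (0.78) without cortex replicate 2. With barcodes ignored Fezf2 (1.07), Bcl11b (1.12), Nr4a2 (1.62) and Foxp1 (0.68) ended. With equal numbers of insertions Ntng1 (0.85), Hs3st4 (1.17) and Nr4a2 (1.56) ended, and with nearest start sites Nr4a2 (0.79), Foxp1 (0.74) and Egr4. Nr4a2 ended with insertions found in several libraries (1.99) or under 5% of another library (1.65) left out, and Nr4a2 and Foxp1 with gene bodies alone (1.65 and 0.77) and a mean of at least 20 insertions (1.79 and 0.78). By DESeq2 Irx1, Prox1, Nr4a2, Foxp1 and Egr4 were not called.

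Of 6715 windows, 400 differed between midbrain and hindbrain, 187 higher in midbrain and 213 in hindbrain. These were 517 and 345 with at least 3 reads, 305 and 114 with the looser low-count filter on window totals, and 94 and 123 by DESeq2. Higher in midbrain were a window in Otx2 (chromosome 14, 48670001 to 48680000, mm10, 5.15-fold), 1 in the predicted gene Gm43517 (chromosome 12, 49390001 to 49400000, 3.66-fold), 1 lying 213356 bp from the start of the neuronal basic helix-loop-helix factor gene Tcf4 (chromosome 18, 69120001 to 69130000, 3.18-fold) and 1 lying 226295 bp from that of Usp25 (chromosome 16, 77240001 to 77250000, 2.22-fold). The window in Gm43517 overlaps the Foxg1 locus as counted here, within its 5 kb flank. Higher in hindbrain were windows in Hoxb3 (chromosome 11, 96320001 to 96330000, 11.6-fold), Meis1 (5.82-fold) and Erbb4 (3.62-fold), and 1 lying 333640 bp from the start of Mki67 (chromosome 7, 136050001 to 136060000, 6.87-fold). The count was 862 with at least 3 reads, 688 without midbrain replicate 3, 252 without midbrain replicate 1, 202 without midbrain replicate 2, 78 without hindbrain replicate 1, 246 without hindbrain replicate 2, 236 without hindbrain replicate 3, 219 with equal numbers of insertions, 158 with barcodes ignored and 217 by DESeq2.

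Over the 3 regions together, 429 of 5842 loci differed in any region by edgeR, 184 without hindbrain replicate 1, 270 without hindbrain replicate 2, 271 without cortex replicate 2, 261 with equal numbers of insertions and 803 without midbrain replicate 3. Insertions lay near genes in every region. Within 5 kb of a transcription start lay 19.8% ± 0.419 of insertions in cortex, 21.1% ± 0.472 in midbrain and 22.1% ± 0.357 in hindbrain (SD, n = 3), where such sequence makes up 7.58% of genome length. Gene bodies held 54.5% ± 0.455, 56.1% ± 1.18 and 55.7% ± 0.840, against 40.4% of length, and 36.3% ± 0.285, 34.4% ± 0.928 and 34.1% ± 0.934 lay in neither, against 56.2%. For the promoter share the exact two-sided permutation p was 0.1 in each of the 3 pairs of regions, the smallest that 3 libraries against 3 allow (0.15 adjusted over 9 comparisons), with every cortex library below every midbrain and hindbrain library. After correction for barcodes already used at dense sites, the shares were 20.7% ± 0.534 in cortex, 22.3% ± 0.585 in midbrain and 22.4% ± 0.755 in hindbrain. Midbrain and hindbrain libraries then overlapped. For gene bodies the exact permutation p was 0.1 for cortex and hindbrain, 0.2 for cortex and midbrain and 0.7 for midbrain and hindbrain.

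Most of the densest sites were shared between regions. Of the 1000 densest windows per library, 76.9% ± 3.11 were shared between libraries of a region (SD over 9 pairs) and 70.0% ± 4.06 between libraries of different regions (27 pairs). Cortex and hindbrain libraries shared 65.5% ± 3.19, cortex and midbrain 72.2% ± 2.12, and midbrain and hindbrain 72.3% ± 2.28. With at least 3 reads, after thinning to 60955 insertions, these shares were 53.4% ± 1.86, 63.1% ± 2.91 and 60.7% ± 3.35. Pairs share libraries and are not independent, and no test was run on them.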

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

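The tests on midbrain replicate 3 and the single-read test of the promoter share were chosen after the result was seen. Insertions on chromosome Y, which the comparisons leave out, numbered 304 in cortex, 50 in hindbrain and 192 in midbrain, above the limit that a count of 0 allows. Per library they were 119, 113 and 72 in cortex, 17, 17 and 16 in hindbrain and 108, 53 and 31 in midbrain. These counts follow library size in part. Scaled to all insertions of a library the regions lay closer together, with the hindbrain libraries still lowest. The sex of the animals is not used here, and the source of these insertions was not tested.

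Telencephalic loci held insertions in the hindbrain libraries, with a median hindbrain to cortex ratio of 0.668 over 23 loci. For the list as a set, reads carried over between libraries as the whole source are argued against by the median ratio with at least 10 reads, 0.471 (95% bootstrap interval 0.131 to 0.736). The list is mixed, with pooled ratios at that read class from 0 at Foxg1, Emx2 and Fezf2 to 2.38 at Bhlhe40. For loci near 0, such as Satb2 (0.0237) and Tbr1 (0.0334), the median cannot argue against carry-over. One even share of cortical cells is argued against by 10 loci whose upper counting limit lay under the median of the pooled ratios, with Foxg1 at 0 hindbrain insertions against 797 in cortex and Cux2 at a ratio of 1.25. Carry-over may explain the single-read insertions: 76.5% of them had the same position and barcode in another library, 31.3 percentage points above randomly drawn barcodes, and a part of the others, with 58.6% and 11.1 points at 2 to 9 reads and 55.5% and 9.04 points at 10 or more. A biological difference of the tissue stays open as untested for the insertions with many reads.

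Midbrain replicate 3 lay below the other midbrain libraries at forebrain interneuron loci, by a median log2 difference of 1.36 with 13 of 14 loci in that direction. With equal numbers of insertions the difference was 0.980. This cannot decide on a lower number of insertions as the cause, since CPM is already scaled to the library total and thinning leaves its expected value unchanged. Reads per insertion were not matched there either. Carried-over reads as the whole cause are argued against, since with at least 10 reads, where single-read insertions are absent, it was 1.498. Forebrain tissue in some midbrain dissections could account for part of it, since 9 of 9 striatal loci outside that list (median 0.969) and 17 of 20 cortical excitatory loci (0.480) went the same way. Telencephalic loci gave 0.174 (14 of 23). That list is mixed, with hindbrain to cortex ratios of 2.38 at Bhlhe40 and 1.27 at Pou3f2, so its median cannot decide on forebrain tissue. Vascular loci, however, gave 1.02 (4 of 4). With at least 10 reads the medians were 1.17 for those striatal loci and 1.08 for cortical excitatory loci. At that read class telencephalic loci gave 0.334 (14 of 23) and vascular loci 0.424 (4 of 4). Among the telencephalic loci, Satb2 then held 200.3, 72.9 and 0 CPM of the class in midbrain replicates 1, 2 and 3. Neurod6 held 176.5, 99.5 and 26.8. A different share of neurons and astrocytes in that library was not tested (astrocyte loci gave -0.504, with 2 of 25 above 0), and a biological difference of the tissue stays open as untested.

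The promoter share was lower in cortex than in hindbrain libraries by 2.29 percentage points. Saturation of the barcodes at dense sites is argued against as the whole cause, since after correction the gap was 1.74 points (SD 0.755). Single-read insertions are argued against, since with at least 3 reads the gap was 2.90 points. Depth, which moved with region, was not tested beyond saturation. Within midbrain the share rose as insertions fell (20.7%, 21.1% and 21.6% in replicates 1, 2 and 3), and cortex went the same way. In hindbrain the largest library had the highest share (22.4%). A biological difference of the tissue stays open as untested.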

How the results depend on the processing

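Leaving out insertions with under 5% of the reads in another library, and the densest windows with at least 3 reads, were alternatives chosen after seeing the data; keeping to TTAA sites, chosen before the data were examined, was not run. Of 172 named results at loci, 113 had no change of call under any alternative in which they were tested, as had 15 of 51 list results. Over the rest, 226 values at loci were weaker, 59 stronger and 2 reversed, and 77 list values weaker, 62 stronger and 3 reversed. Direction was compared only where the main or the alternative value was called, so turns of uncalled results are not counted. Loci and lists that an alternative removed were not checked under it. Contrasts are ordered cortex against hindbrain, cortex against midbrain, midbrain against hindbrain, and the cause was not tested except where fewer insertions or libraries are the setting. With an estimated correlation 0, 2 and 0 lists were called, and with fry 2 in each of the last pair of contrasts. With no low-count filter there were 97 loci for cortex against midbrain and 10 lists for midbrain against hindbrain, where brainstem genes turned towards hindbrain (adjusted p = 0.00168). With a mean of at least 20 insertions 3 lists were called for cortex against hindbrain, and midbrain transcription factors turned between midbrain and hindbrain (0.0415). With nearest start sites there were 90 loci for cortex against midbrain and 8 lists for midbrain against hindbrain, and Mef2c (log2 fold change -0.12, cortex against hindbrain) and Pde10a (0.0333, cortex against midbrain) reversed. With at least 3 reads 369 loci and 862 windows were called for midbrain against hindbrain, vascular genes turned between cortex and midbrain (0.802), hindbrain shares were 22.6% (promoter), 57.0% (gene body) and 32.8% (neither), and 68.5% and 59.1% of the densest windows were shared within and between regions. With barcodes ignored there were 30 and 129 loci in the last pair of contrasts, 7 lists for midbrain against hindbrain, 593, 92 and 158 windows, promoter shares of 16.2%, 19.9% and 18.1% and gene body shares of 56.7%, 57.9% and 58.4% in cortex, hindbrain and midbrain, 35.9% and 33.1% in neither in cortex and hindbrain, and 65.9% and 59.7% of densest windows shared. Leaving out insertions found in several libraries gave 751 and 157 windows in the first pair of contrasts. With equal numbers of insertions there were 318, 22 and 124 loci, 261 in any region, 4 and 5 lists in the first pair of contrasts, and 542, 79 and 219 windows. Leaving out insertions under 5% gave 674 windows for midbrain against hindbrain. DESeq2 gave 370 and 139 loci for cortex and for midbrain against hindbrain, and 805, 139 and 217 windows. With 1 kb to the start site promoter shares were 8.27%, 9.50% and 8.87%, and 40.5%, 38.4% and 38.5% lay in neither.

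A block for replicate number gave 910, 172 and 449 loci, 867 in any region, and 517 and 752 windows in the last pair of contrasts. It also brought 2 list results past the threshold that were not called without it. The labels do not say that equal numbers share an animal. Deviations from the region means correlated positively in 8 of 9 same-number pairs of libraries, with 0.378 for cortex and midbrain replicates 1 and 0.342 for cortex and midbrain replicates 3, and between -0.00208 and 0.0918 in the other 7. Each cortex library correlated best with its own number among the midbrain libraries, but cortex replicate 3 correlated more with hindbrain replicate 2 (0.0513) than with hindbrain replicate 3 (0.0297), and hindbrain replicate 2 more with midbrain replicate 3 (0.0378) than with midbrain replicate 2. The numbers were therefore not taken as pairs, and a shared source of equal numbers in cortex and midbrain stays open. In both regions insertions fell and the single-read share rose from replicate 1 to replicate 3. That shared order of depth was not told apart from a shared source.

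With each library left out, loci ranged from 193 (without hindbrain replicate 1) to 757 (without midbrain replicate 3) for cortex against hindbrain, from 15 (without cortex replicate 2) to 125 (without midbrain replicate 3) for cortex against midbrain, from 49 (without hindbrain replicate 1) to 489 (without midbrain replicate 3) for midbrain against hindbrain, and from 184 (without hindbrain replicate 1) to 803 (without midbrain replicate 3) in any region. Windows ranged from 586 to 1709, 120 to 378 and 78 to 688, and lists from 5 to 10, 7 to 9 and 4 to 6.

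Among splits of the 6 libraries of a contrast, fitted without the remaining region so that counts differ from those of all 9 libraries, the real one gave 702, 39 and 206 loci and 1475, 190 and 395 windows, the highest other 0 in each, and 1 of 10 splits gave as many; the splits are too few for a share under 0.05. Of 100 drawn splits of the 9 libraries, the real one included, 1 gave as many loci in any region, the real one with 429 against 139 for the highest other. A chance split of these libraries is thus argued against. The splits cannot tell region from depth or from the single-read share, which moved with region.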

Other observations

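Some of the densest windows lay outside protein-coding genes and were dense in all 3 regions. A window on chromosome 13 (84750001 to 84760000, mm10), 429408 bp from the start of Ccnh, held 2127 ± 131 CPM in cortex, 2116 ± 393 in midbrain and 1536 ± 169 in hindbrain (SD, n = 3). A window 205967 bp from the start of Mef2c, a neuronal transcription factor gene, held 1075 ± 60.4, 1275 ± 211 and 1465 ± 157, and a window 200405 bp from the start of Sox2, a gene of neural stem cells and glia, 1053 ± 63.3, 1217 ± 163 and 1325 ± 2.12. These windows were chosen after their values were seen.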
